A study of Mus musculus with 4 samples.

How the data were processed

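Expression was measured on single-colour Affymetrix arrays hybridised with biotin-labelled total RNA from murine embryonic stem cells (CM7/1). The deposited values are log2 probe set summaries made with RMA, per the labels. RMA corrects the background, normalises arrays by quantiles and summarises the probes of a set. Its version, the software, the chip description file and the genome build are not given in the sources used here. The log2 scale was read from the range of the values, 2.67 to 15.2. The sorted values of the 4 arrays agreed within 0.0024, and each array's median was 6.05, so the arrays share a single distribution and a change of all genes together cannot be seen in them. Scanner files were not used here, and depth has no counterpart in these values.

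Each sample was assigned from its title to Hey1 uninduced, Hey1 induced, Hey2 uninduced or Hey2 induced, with 1 array per group. Of the 45101 probe sets, the platform annotation gave 34958 a single gene symbol, 932 several and 9211 none, the last including 64 control probe sets. The gene identifiers of 34754 single-symbol probe sets matched the RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols needed updating. That assembly's coordinates are not printed, since the array's build is not given in the sources used here. Only probe sets with a single symbol were used. Each gene was represented by the probe set with the highest mean over the 4 arrays, and a gene was compared if the highest of its 4 values reached 6.05, the median of all values. This left 12098 of 18194 genes, of which 7251 had more than 1 probe set above the filter.

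For each line the log2 value of the uninduced array was subtracted from that of the array labelled induced, and genes at 2-fold or more were counted. The uninduced arrays were compared in the same way, as were the differences of the lines. The common response was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, line as a block, Benjamini-Hochberg adjustment at 0.05). Nothing in the labels says whether the arrays came from separate cultures, so these p-values measure only the spread between these samples. Whether a gene list stood apart in a line was described by the percentile of its median difference among 10000 random lists of the same size matched on mean level in 20 bins, with percentiles under 2.5 or over 97.5 taken as outside the random range. These percentiles describe the arrays and are not p-values. P-values adjusted over a list alone were not adjusted for the number of lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for everything else.

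The limma fit was tested on simulated data, averaged over 20 draws of the 12098 genes with 200 changed in the common response. The changes were of 0.5, 1 and 2 on the log2 scale, in about equal numbers. It recovered 1.4% of genes changed by 0.5, 69.9% of those changed by 1 and 97.4% of those changed by 2, and 6.6% of all calls were false. The many large changes ease the adjusted threshold for the others. In the real arrays 1 gene was at least 3-fold higher in both lines and 0 were lower. These rates therefore do not give the power of the fit on the real arrays. A random list of 20 genes moved by 0.5 in the Hey1 line came out at the 100th percentile and an unmoved list at the 14.6th.

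The comparisons and their tests, the 18 gene lists, the rule for named genes and the alternatives named first below were fixed before the data were examined. The tests of possible explanations were set later, some of them after their results were seen. The rule named the probe sets of Hey1 and Hey2, up to 12 genes per direction in each line with a difference of at least 2-fold, the 10 genes per direction with the largest smaller difference of the 2 lines, and the 6 genes per direction that differed most between the lines' responses and between the uninduced arrays. It added from each list the 4 members with the largest mean difference and any member past 2-fold, and left out predicted genes and clone names. Other genes in the text are list members, or members of counts of 5 or fewer, and were chosen after their values were seen. The lists covered the Notch pathway, genes described elsewhere as repressed by Hey factors, naive and primed pluripotency, mesoderm, cardiac, endoderm, neuroectoderm, trophoblast and fibroblast markers, the two-cell-like state, BMP and TGF-beta signalling, p53 targets, mitosis, the Atf4 stress response, hypoxia and glycolysis, imprinted genes and housekeeping genes. Older symbols in the lists were updated through synonyms, except names that are another gene's own symbol. Lists of germline genes and of serum response factor targets were added after the data were seen.

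The alternatives fixed in advance were no level filter, a filter at the 75th percentile of all values (8.31), cyclic loess, centring on the median, an offset of 32 on the linear scale, the mean of a gene's probe sets, every probe set on its own, thresholds of 1.5-fold and 3-fold, no block, a robust prior with a trend, an adjusted p of 0.1 and random lists not matched on level. Alternatives added after seeing the data were the uninduced array of the other line as the reference, leaving out the two-cell-like list, removing a trend on genomic length and leaving out each array in turn.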

Results

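Gene expression was measured in murine embryonic stem cells (CM7/1) described as overexpressing Hey1 or Hey2, basic helix-loop-helix transcriptional repressors that act downstream of Notch receptors. The cells that carried each factor, called the Hey1 line and the Hey2 line here, were profiled without induction and after 1000 ng/ml doxycycline for 48 h. The series title gives its subject as the regulation of target genes by Hey factors. Total RNA was hybridised to 4 Affymetrix arrays, with 1 array in each of the groups Hey1 uninduced, Hey1 induced, Hey2 uninduced and Hey2 induced. The series states that there were no replicates, so a difference between 2 arrays has no replicate check and is given without a p-value, and the number of arrays limits the precision. Of 18194 genes named on the array, 12098 passed the filter on level and were compared. The scaled median absolute deviation of the log2 difference across genes was 0.16 between the arrays of the Hey1 line, 0.22 between those of the Hey2 line and 0.29 between both uninduced arrays.

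The array gave no sign of the introduced genes at their own probe sets. The single Hey1 probe set read 6.73 on the log2 scale in uninduced and 6.51 in induced cells of the Hey1 line, a difference of -0.23, and its difference in the Hey2 line was -0.47. The single Hey2 probe set lay at the 22.9th percentile of all probe sets, below the level filter. Its difference was 0.09 in the Hey2 line and -0.32 in the Hey1 line. Whether these probe sets read the introduced transcripts is not given in the sources used here. The measured values therefore went against the labels or did not test them, and every direction below is that of the array labelled induced minus the uninduced array of the same line.

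In the Hey1 line, most genes that differed at least 2-fold were higher in the array labelled induced. The largest difference was that of the clone BC080696 (4.93 on the log2 scale), and predicted genes and clone names are otherwise left out here. Pramel18, of a family expressed in germ cells, was 26.9-fold higher, and Usp17la, a deubiquitinase gene of the two-cell embryo, was 14.6-fold higher. Ubtfl1, a gene of preimplantation embryos, was 10.7-fold higher, but its uninduced value of 3.98 lay far below the level filter, so the size of this fold is uncertain. Other genes well above 2-fold were the heat shock gene Hspa1a (5.43-fold), Ms4a4d (4.63-fold), Sp110 (4.04-fold), Psors1c2 (3.89-fold), the growth factor gene Fgf1 (3.74-fold), Clnk (3.33-fold), Rfpl4b (2.88-fold), Calml4 (2.88-fold) and the apoptosis gene Pmaip1 (2.80-fold). Uninduced values of Ms4a4d (4.285), Fgf1 (5.42) and others of these genes also lay below the filter. The genes at least 2-fold lower were Zic2 (-1.59 on the log2 scale), the Nodal antagonist gene Lefty2 (-1.14), Dpysl3 (-1.11) and Zic5 (-1.05). In all, 53 genes were at least 2-fold higher and 4 at least 2-fold lower. These counts had no test. Set against the uninduced array of the Hey2 line they became 252 and 135, and the differences of Zic2 and Zic5 turned to 0.055 and 0.31.

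In the Hey2 line, the largest differences in the array labelled induced were higher values of Cpeb1, St8sia6 and Clnk and lower values of Zic5, Trh and Lefty1. The translational regulator gene Cpeb1 was 4.29-fold higher, and the meiosis genes Meioc and Tex15 were 3.17-fold and 3.05-fold higher. Taf7l, a TFIID subunit gene of male germ cells, was 2.98-fold higher. St8sia6 (3.67-fold), Clnk (3.63-fold), Ccdc18 (3.04-fold), She (3.03-fold), Lpar4 (2.99-fold), Calcoco2 (2.98-fold), Ccdc88a (2.92-fold) and Prss35 (2.92-fold) completed the 12 largest once predicted genes and clone names, such as AU041133, were left out. Among the lower genes, Zic5 had a difference of -1.92, the thyrotropin-releasing hormone gene Trh of -1.76, and the Nodal antagonist genes Lefty1 and Lefty2 of -1.74 and -1.51. Id2, a target of BMP signalling, had -1.59, the smooth muscle actin gene Acta2 had -1.51 and the Notch ligand gene Jag1 had -1.38. The others were Cd24a (-1.48), Fgf18 (-1.47), Sgms2 (-1.45), Trim13 (-1.36) and Fgf1 (-1.22, with both values below the level filter). In all, 83 genes were at least 2-fold higher and 29 at least 2-fold lower, with no test. Across genes the difference went with genomic length (Spearman's rho 0.13, against 0.02 in the Hey1 line). The log2 difference between the 3' and 5' control probe sets, a sign of RNA quality, was 0.67 in uninduced and 0.96 in labelled induced cells of this line for Tfrc (0.95 and 0.84 in the Hey1 line). It was 1.33 and 1.56 for Pcx (1.38 and 1.43) 0.39 and 0.42 for Actb (0.48 and 0.51) and 0.012 and 0.032 for Gapdh (0.040 and 0.042). With the uninduced array of the Hey1 line as the reference the counts became 135 and 94, and the differences of St8sia6, Prss35 and Acta2 turned to -0.71, -0.82 and 1.12.

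**Figure D1:**
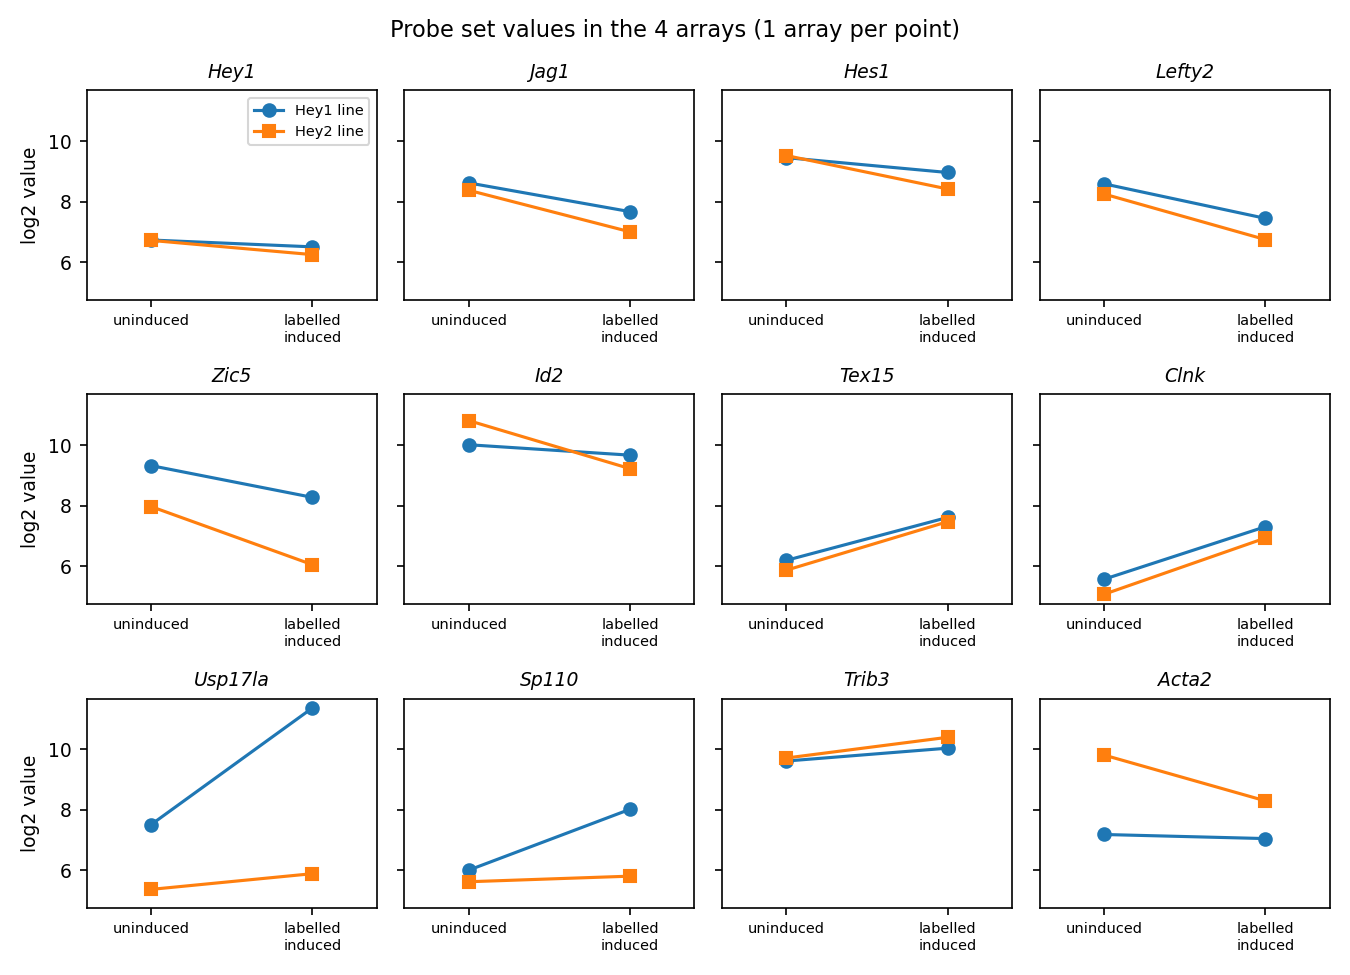
Log2 probe set values (vertical axis) of 12 genes in the uninduced array and the array labelled induced of the Hey1 line (blue circles) and the Hey2 line (orange squares), with 1 array per point and no error bars. Jag1, Lefty2 and Zic5 lay lower and Tex15 and Clnk higher in the labelled induced array of both lines, Usp17la and Sp110 differed mainly in the Hey1 line, and Acta2 started from 9.81 in the uninduced Hey2 line against 7.18 in the uninduced Hey1 line.

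The uninduced arrays of the 2 lines differed from each other by more than either line differed from its labelled induced array. Grb10, an imprinted gene that encodes a growth factor receptor adaptor, was higher in the uninduced Hey2 line by 3.98 on the log2 scale. The muscle genes Acta2 and Myl9 were higher there by 2.63 and 2.10, and Aim2 and Plac8 by 2.48 and 2.29. Rnf128 read 9.04 there against 7.04 in the uninduced Hey1 line. Genes lower in the uninduced Hey2 line were Cabp4 (-2.67), St8sia6 (-2.58), Slc4a5 (-2.57), Cntnap2 (-2.46), Gap43 (-2.42) and Prss35 (-2.36). This background, measured in the same way as the differences within the lines, held 100 genes at least 2-fold higher and 137 at least 2-fold lower in the Hey2 line. The arrays labelled induced differed in the same direction for Grb10 (12.65 in the Hey2 line against 9.18 in the Hey1 line), Aim2 (7.90 against 5.67), Slc4a5 (5.17 against 7.50) and Gap43 (6.86 against 9.04). They lay closer together than the uninduced arrays for Acta2 (8.30 against 7.04), St8sia6 (6.84 against 7.96) and Prss35 (6.96 against 7.99). These differences had no test.

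Many of the differences were shared by the 2 lines. The genes with the largest smaller difference of the 2 lines on the higher side were Clnk (1.74 in the Hey1 line and 1.86 in the Hey2 line), Calml4 (1.53 and 1.45), Tex15 (1.42 and 1.61), Ms4a4d (2.21 and 1.31), the prostaglandin synthase gene Ptgs2 (1.36 and 1.30), Taf7l (1.27 and 1.58), Calcoco2 (1.16 and 1.57), Lpar4 (1.09 and 1.58), Slc25a31, the germ cell ADP/ATP carrier gene (1.18 and 1.07), and Cpeb1 (1.05 and 2.10). On the lower side stood Lefty2 (-1.14 and -1.51), Dpysl3 (-1.11 and -1.19), Zic2 (-1.59 and -1.06), Zic5 (-1.05 and -1.92), Jag1 (-0.95 and -1.38), Lefty1 (-0.94 and -1.74), Pcolce2 (-0.83 and -0.97), the neural transcription factor gene Sox1 (-0.78 and -1.07), Cnpy1 (-0.94 and -0.73) and Zfhx3 (-0.73 and -0.83). The other probe set had -0.55 and -0.78 for Jag1 and -0.0093 and -0.36 for Sox1. Other probe sets of Dpysl3 were as weak as -0.56 and -0.63. Both Hey2-line values lay below the level filter for Ms4a4d (3.64 and 4.95), Ptgs2 (4.41 and 5.71) and Zic2 (5.641 and 4.585). The sizes of their Hey2-line differences are therefore uncertain, although these genes count among those shared at 2-fold. At 2-fold, 12 genes were higher in both lines where independent lists of these sizes would share 0.36, and 4 were lower in both where they would share 0.01. The lines share no array. Of the 57 genes past 2-fold in the Hey1 line, 48 had the same sign in the Hey2 line, and of the 112 past it in the Hey2 line, 101 had the same sign in the Hey1 line, where 63.6% of all genes compared had the same sign in both. Across genes, which are not independent replicates, the differences of the 2 lines had a Pearson's r of 0.41 and a Spearman's rho of 0.37. The Hey2-line differences of Ptgs2 and Slc25a31 turned to -0.64 and -0.037 against the uninduced array of the Hey1 line.

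**Figure D2:**
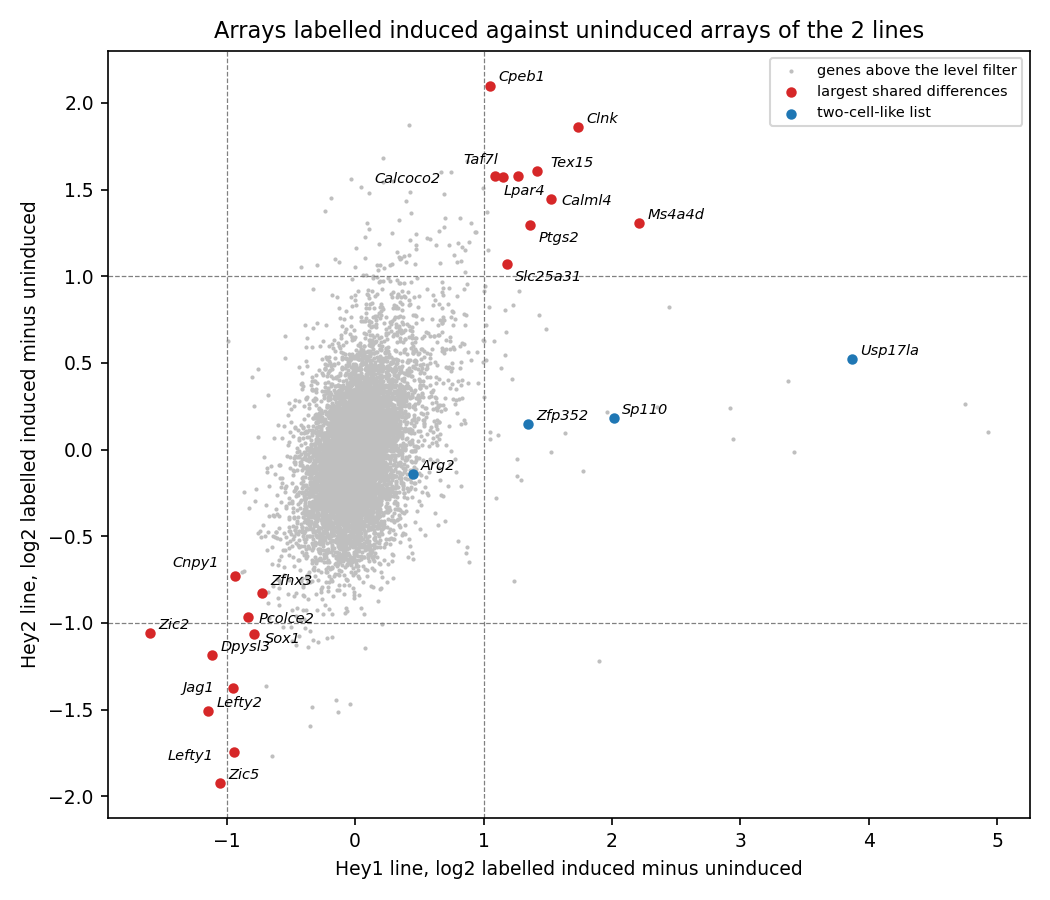
Log2 difference between the array labelled induced and the uninduced array in the Hey1 line (horizontal axis) and the Hey2 line (vertical axis), with 1 point per gene for the 12098 genes that passed the level filter and dashed lines at 2-fold. The largest shared differences (red) lie at the upper right and lower left, and the two-cell-like genes (blue) lie to the right, with Usp17la at 3.87 in the Hey1 line and 0.52 in the Hey2 line.

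The differences of the lines were also set against each other gene by gene. The value was more positive in the Hey1 line by at least 2-fold for 45 genes and in the Hey2 line for 36 genes, 81 in all. On the log2 scale, and with predicted genes and clone names left out, the Hey1 line exceeded the Hey2 line most for Pramel18 (4.75 against 0.26), Ubtfl1 (3.41 against -0.02), Usp17la (3.87 against 0.52), Fgf1 (1.90 against -1.22), Sbsn (1.23 against -0.76) and Sp110 (2.02 against 0.18). Ubtfl1 lay far below the level filter in the uninduced Hey1 (3.978), uninduced Hey2 (3.281) and induced Hey2 (3.265) arrays, so its exact place is uncertain. Pramel18, Usp17la and Sp110 also lay below the filter in both Hey2-line arrays. With the same genes left out, the Hey2 line exceeded the Hey1 line most for Zc3h6 (1.45 against -0.19), Gsta3 (1.38 against -0.23), Selenon (1.05 against -0.42), Pkhd1 (1.52 against 0.05), St8sia6 (1.87 against 0.42) and Zfp182 (1.48 against 0.11). Zc3h6, Selenon and Pkhd1 reached the level filter only in the Hey2-line array labelled induced. Their Hey1-line differences lie between values below the filter, so the sizes of these gaps are uncertain. Fgf1 was the only gene past 2-fold in opposite directions, and its other probe set had 0.42 in the Hey1 line and -0.94 in the Hey2 line. Fgf1 reached the level filter only in the Hey1-line array labelled induced (7.32). Its Hey2-line fall lies between values below the filter (5.95 and 4.73), so the size of that fall is uncertain. The other probe set of Sbsn had 2.13 and 0.18, higher in both lines, and that of Zfp182 had 0.09 and 0.21, with little difference between them. The other probe sets of St8sia6 reached up to 1.08 in the Hey1 line and down to 0.64 in the Hey2 line. This comparison uses all 4 arrays and leaves nothing to test it with. The Hey2-line difference of Gsta3 turned to -0.65 against the uninduced array of the Hey1 line.

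The response common to the lines was tested with limma, with the line as a block, which treats induction of Hey1 and Hey2 as repeats of a single treatment. No gene passed an adjusted p of 0.05 in either direction, and the lowest adjusted p was 0.237. The mean difference was 1.80 ± 0.09 (SE) for Clnk, 1.49 ± 0.08 for Calml4, 1.51 ± 0.09 for Tex15, -1.15 ± 0.08 for Dpysl3 and -1.32 ± 0.12 for Lefty2, each from 2 lines and at that adjusted p. At an unadjusted p of 0.05, 835 genes were higher and 763 lower in the arrays labelled induced, where chance would give 604.9 in all. The fit had 1 residual degree of freedom per gene. With a prior variance that follows the level and is robust to outliers, limma called 241 genes higher and 192 lower, and on the 7355 genes above the stricter level filter it called 3 higher (Calml4, Slc25a31 and AA414768) and 1 lower (Dpysl3). A fit without the Hey2 induced array, and without the block, sets the Hey1 induced array alone against the uninduced arrays of both lines. It does not measure a common response. Pramel18 and Ubtfl1 had differences of 5.09 and 3.76 in that fit, but of 0.26 and -0.02 within the Hey2 line.

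Genes of the Notch pathway, of which 29 were compared, stayed within the random range as a list in both lines. The list's median difference was -0.03 in the Hey1 line, the 30.1th percentile of random lists matched on level, and -0.08 in the Hey2 line, the 14.7th percentile. In the Hey1 line the list lay at the 0.94th percentile with the stricter level filter and at the 0.03th with the mean of each gene's probe sets. Single members were lower in both lines, among them the ligand gene Jag1 (-0.95 and -1.38), the effector gene Hes1 (-0.49 and -1.11), the receptor gene Notch1 (-0.48 and -0.52) and the ligand gene Dll1 (-0.20 and -0.73). The other probe set of Notch1 had -0.05 and -0.50. No member passed the common-response test over all genes, and 1 member, Jag1, passed when p was adjusted over the list alone (adjusted p = 0.030 by limma). Of 15 genes described elsewhere as repressed by Hey factors, 6 passed the level filter. Their median was -0.11 in the Hey1 line (10.7th percentile) and -0.40 in the Hey2 line (0.25th percentile). In the Hey2 line Jag1, Acta2 and the receptor gene Kdr (-0.55) were lower, Tbx3 was higher by 0.72, and the list lay within the random range without the level filter (13.2th percentile), with the mean of probe sets (2.80th) and against the uninduced array of the Hey1 line (7.06th), where Acta2 turned to 1.12. In this list too only Jag1 passed with p adjusted over the list alone.

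As a list, genes of BMP and TGF-beta signalling were lower in the arrays labelled induced of both lines, with members in both directions. The median of the 15 compared members was -0.17 in the Hey1 line (0.02th percentile) and -0.34 in the Hey2 line, below all 10000 random lists, and 4 and 5 of the 15 were above 0. Besides Lefty1 and Lefty2, the BMP target genes Id2 (-0.35 and -1.59), Id1 (-0.17 and -0.84) and Id4 (-0.51 and -0.61), the ligand genes Bmp4 (-0.40 and -0.34) and Bmp7 (-0.45 and -0.55) and the SMAD corepressor gene Skil (-0.40 and -0.98) were lower. The inhibitory SMAD genes Smad6 (0.61 and 0.84) and Smad7 (0.13 and 0.36) and the BMP target gene Id3 (0.20 and 0.20) were higher. In the common-response test, 7 members passed with p adjusted over the list alone and 0 over all genes, and Id1, Id2, Id3 and Smad7 passed neither. Without the level filter the Hey2-line list lay at the 16.8th percentile.

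The core pluripotency genes Pou5f1 and Sox2 differed little, by -0.02 and 0.06 and by 0.13 and -0.01 in the Hey1 and Hey2 lines. The 27 genes of the naive pluripotency list had a median of -0.08 in the Hey1 line (1.07th percentile) and -0.01 in the Hey2 line (39.0th percentile). In the Hey1 line 9 of them were above 0 and in the Hey2 line 12. Klf4 (-0.13 and 0.61), Tfcp2l1 (0.03 and 0.55) and Tbx3 (-0.39 and 0.72) were higher in the Hey2 line. With p adjusted over the list alone, 5 members fell in the common response: Lefty1, Lefty2, Klf2 (-0.60 and -0.66), Tcl1 (-0.59 and -0.75) and Nr0b1 (-0.52 and -0.47). Over all genes 0 passed. Of the 11 epiblast and primed genes, whose medians of 0.03 and -0.13 lay at the 72.8th and 12.7th percentiles, the de novo DNA methyltransferase gene Dnmt3a rose (0.76 and 0.72) and Zic2 and Fgf15 (-0.40 and -0.78) fell with p adjusted over the list alone, and 0 passed over all genes. Foxd3 had -0.68 and -0.13. Against the uninduced array of the Hey2 line the naive list's Hey1-line percentile was 26.1, and against that of the Hey1 line the epiblast list's Hey2-line median lay below all random lists.

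Stress and p53 genes differed in both lines. Genes of the integrated stress response, driven by the transcription factor Atf4, were higher: the median of 20 members was 0.15 in the Hey1 line and 0.37 in the Hey2 line, above all 10000 random lists in each. In the Hey1 line 16 of the 20 were above 0 and in the Hey2 line 20 of 20. With p adjusted over the list alone, Trib3 (0.43 and 0.69), Cebpb (0.56 and 0.42), Nupr1 (0.48 and 0.49), Ddit3 (0.38 and 0.56) and Ddit4 (0.41 and 0.36) rose in the common response, and 0 passed over all genes. The other probe set of Cebpb had 0.16 and 0.35. Atf3 had 0.30 and 0.66. The 14 p53 targets had medians of -0.20, below all random lists, and -0.17, at the 0.06th percentile. Perp (-0.38 and -0.92), Phlda3 (-0.46 and -0.27) and Bbc3 (-0.19 and -0.44) were lower, while Pmaip1 was higher (1.48 and 0.69), and 0 members passed either adjustment. Against the uninduced array of the Hey2 line the Hey1-line p53 list lay at the 6.31th percentile.

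Genes of the two-cell-like state, a rare state of embryonic stem cells that resembles the two-cell embryo, were higher in the Hey1-line array labelled induced. Of 15 listed genes 6 had a probe set with a single symbol and 4 were compared. Of these, Sp110 and Arg2 passed the level filter only through the Hey1-line array labelled induced. Usp17la, Sp110 and Zfp352 differed by 3.87, 2.02 and 1.34 in the Hey1 line and by 0.52, 0.18 and 0.15 in the Hey2 line, and Arg2 by 0.45 and -0.14. The list's median was 1.68 in the Hey1 line, above all random lists, and 0.17 in the Hey2 line, at the 90.7th percentile. Between the uninduced arrays it was -0.86, Hey2 line minus Hey1 line, at the 0.03th percentile. Usp17la belongs to a family of near-identical copies, whose signals a probe set may not separate.

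**Figure D3:**
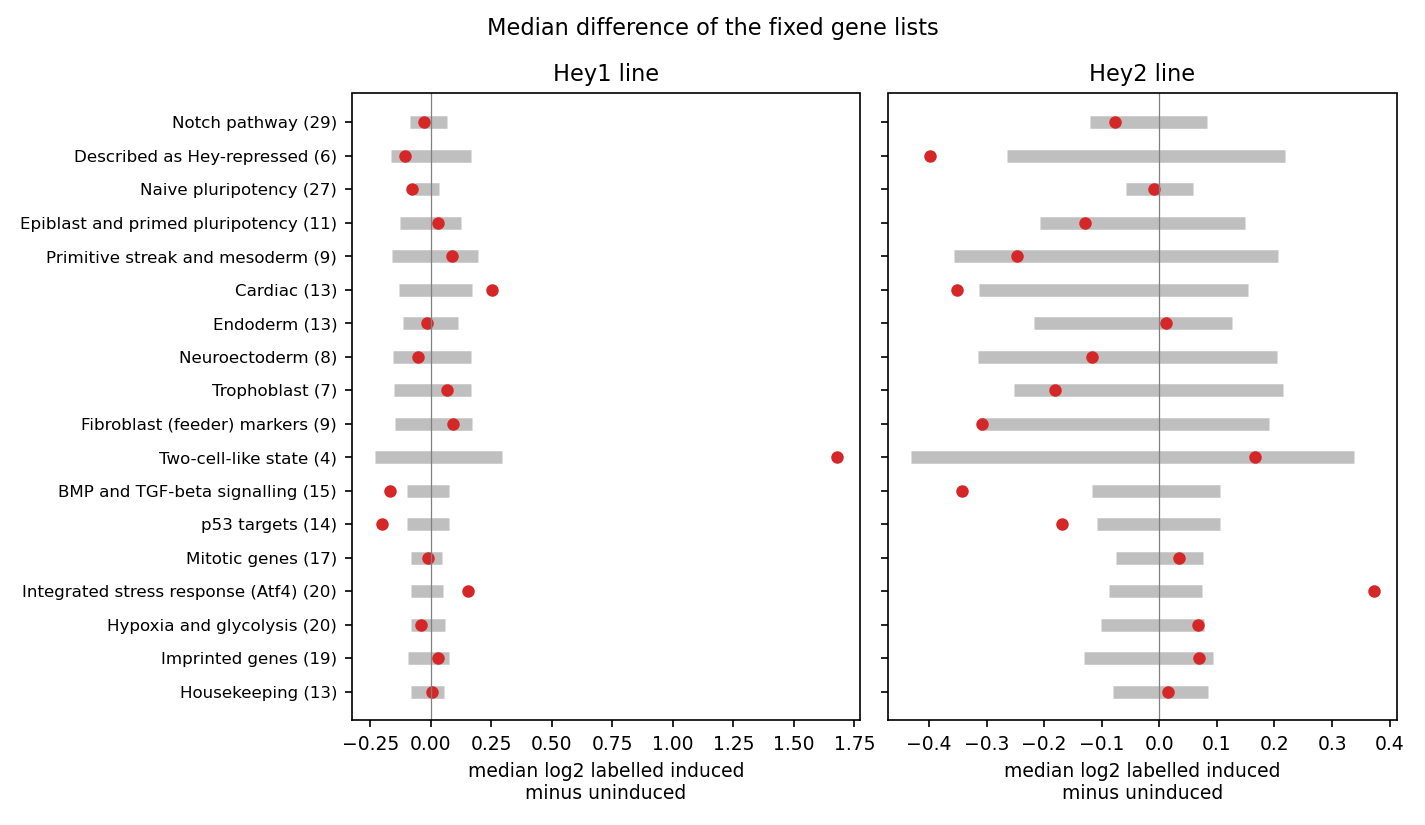
Median log2 difference between the array labelled induced and the uninduced array (red points, horizontal axis, with a different scale in each panel) of the 18 fixed gene lists in the Hey1 line (left) and Hey2 line (right), with the number of genes compared in brackets. Grey bars span the central range of the medians of 10000 random lists of the same size matched on level. The two-cell-like list lies at 1.68 in the Hey1 line, and the lists of BMP and TGF-beta signalling and of p53 targets lie below the grey bars and the stress response list above them in both lines.

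Markers of differentiated cells went in both directions within each list, and no test covered the lists together. In the Hey2 line the medians were below 0 for the cardiac, mesoderm (-0.25), neuroectoderm (-0.12), trophoblast (-0.18) and fibroblast lists, and 0.01 for the endoderm list. The 13 cardiac genes had a median of 0.25 in the Hey1 line (99.8th percentile) and -0.35 in the Hey2 line (1.13th percentile), yet 9 of the 13 had the same sign in both lines. The sarcomere genes Ttn (1.03 and 1.37) and Myh6 (0.46 and 0.88) were higher, and the transcription factor gene Nkx2-5 (-0.51 and -0.75) and Tnni1 (-0.28 and -0.57) were lower. With p adjusted over the list alone 7 passed the common-response test, and 0 over all genes. Both percentiles were lost without the level filter (75.9 and 2.74) and after cyclic loess (94.7 and 3.39). Medians lay at the 81.4th and 15.5th percentiles for 9 genes of the primitive streak and mesoderm, with Foxf1 at -0.31 and -0.73, Hand1 at 0.21 and -0.74 and Sp5 at 0.15 and 0.28. They lay at the 42.5th and 75.6th percentiles for 13 endoderm genes, with Sox7 at 0.48 and 1.18, Lamb1 at -0.11 and -0.61, Hnf4a at -0.12 and -0.52 and Hhex at 0.14 and 0.39. For 8 neuroectoderm genes they lay at the 25.6th and 34.9th percentiles, with Sox1 passing over the list alone, and for 7 trophoblast genes at the 81.6th and 7.87th, with Tfap2c at 0.60 and 0.27. For 9 markers of fibroblasts, a possible feeder cell, the medians of 0.09 and -0.31 lay at the 86.8th and 2.83th percentiles. In that list Acta2 and Tagln had -1.51 and -0.87 in the Hey2 line, and Thy1 had 0.67 and 0.22.

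The remaining lists stayed within the central range of random lists in both lines. The 17 mitotic genes lay at the 60.6th and 82.0th percentiles, with the proliferation marker gene Mki67 at 0.13 and 0.91. The 20 genes of hypoxia and glycolysis lay at the 22.0th and 96.1th percentiles, with Egln3 at 0.51 and 0.58 and Vegfa at 0.59 and 0.34. The 19 imprinted genes lay at the 81.4th and 93.7th percentiles, and Sgce (1.16 and 0.81), Peg10 (0.67 and 0.68) and Magel2 (0.52 and 0.58) rose with p adjusted over the list alone, with 0 over all genes. The 13 housekeeping genes lay at the 74.4th and 65.6th percentiles, with Gusb at 0.17 and 0.18 and Polr2a at -0.08 and -0.21.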

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

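Of the tests in this part, that of the uninduced Hey2-line array and that of gene length were set before their results were seen, and those of the two-cell-like genes and of the Hey1 and Hey2 probe sets were chosen after.

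Some results differed between the lines in direction, and these differences were not tested, since each rests on 1 array per group. Fgf1 was higher in the Hey1 line and lower in the Hey2 line, with a difference of the 2 of -3.12 on the log2 scale (Hey2 line minus Hey1 line). Both Hey2-line values (5.95 and 4.73) and the uninduced Hey1-line value (5.42) lay below the level filter, so this size is uncertain. The other probe set of Fgf1 also went both ways but stayed under 2-fold, with 0.42 and -0.94. Sbsn differed likewise, with -1.99, but its other probe set was higher in both lines (2.13 and 0.18). The cardiac list had medians of opposite sign, -0.60 apart, although 9 of its 13 members had the same sign in both lines. Most of its members lay near the level filter. Signals also appeared in probe sets that the comparisons leave out. Of 3019 probe sets without a single gene symbol above the level filter, 22 were at least 2-fold higher in the Hey1-line array labelled induced and 0 at least 2-fold lower, and in the Hey2 line 72 were higher and 2 lower. Between the uninduced arrays 11 of them were at least 2-fold higher and 58 at least 2-fold lower in the Hey2 line. A control probe set for mouse B1 repeats was higher by 0.43 on average over the lines, 0.40 in the Hey1 line and 0.46 in the Hey2 line, while the 45 bacterial and phage controls differed by at most 0.375 in any comparison. Other mouse controls differed too: a Pcx control had -0.54 and the 3' Tfrc control 0.40 in the Hey2 line, and another mouse control (b2) had 0.23 in the Hey1 line and -0.20 in the Hey2 line.

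The first pattern weighed is the high value of two-cell-like genes in the Hey1-line array labelled induced. Signal shared among copies of multicopy families would leave members outside them without such a rise. Sp110, Zfp352 and Arg2 were taken as outside them, and their median was 1.34, although that is 3 genes and Arg2 lay at 0.45. This argues against such signal as the whole cause only as far as these genes have no near-identical copies. Whether that holds, for Sp110 in particular, was not checked here. Raised values of all genes of that level in this array are argued against by the list's position above all level-matched random lists, at the 100th percentile. Sp110 and Arg2 passed the level filter only through this array, but without that filter the list also lay at the 100th percentile. The percentile is the pattern itself set beside genes of like level, and adds no independent support. A share of two-cell-like cells that varies between cultures for reasons other than induction stays open, since 1 array per group does not measure it. The list also differed between the uninduced arrays, by -0.86, a smaller size than the 1.68 within the Hey1 line. That difference decides nothing, because every compared member passed the level filter only through Hey1-line arrays. An effect of Hey1 itself, which the design names, is also open, because a single array per group cannot separate it from a difference between cultures.

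The second is the larger number of genes past 2-fold in the Hey2 line, an order that turned at 3-fold (16 higher and 1 lower in the Hey1 line, 8 and 4 in the Hey2 line) and against the uninduced array of the other line (252 and 135, then 135 and 94). If the uninduced Hey2-line array stood apart from the other 3, under 25% of the Hey2-line genes past 2-fold were to keep their difference against the uninduced array of the Hey1 line, and 24.1% did (27 of 112, exact binomial interval 16.5% to 33.1%, which spans the bound), against 73.7% of the Hey1-line genes (42 of 57) in the reverse exchange. The interval counts genes as independent trials, which they are not, and does not measure variation between arrays or cultures. The share of 24.1% lies below the preset bound, but the exchange also brings every lasting difference between the lines into the comparison. It cannot tell such a difference from an uninduced Hey2-line array that stands apart, whether through the array or the state of its culture. The shares of the lines are also not alike, since a larger part of the Hey1-line genes passed 3-fold. A stronger effect of Hey2 remains untested. A trend with genomic length, as RNA integrity could give, is argued against as the whole cause: with the trend removed, 113 genes passed in the Hey2 line and 60 in the Hey1 line. RNA quality apart from that trend stays open. The 3' minus 5' difference of Tfrc and Pcx was higher in the Hey2-line array labelled induced than in its uninduced array (0.96 against 0.67, and 1.56 against 1.33). That of Actb was 0.42 against 0.39 and that of Gapdh 0.032 against 0.012. In the uninduced and labelled induced Hey1-line arrays it was 0.95 and 0.84 for Tfrc and 1.38 and 1.43 for Pcx. For Tfrc the uninduced Hey2-line array therefore stood lowest, and for Pcx the labelled induced Hey2-line array stood highest.

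The third is the lack of a higher Hey1 or Hey2 value in the arrays labelled induced. An exchange of the labels within 1 of the 2 lines is argued against by the positive correlation of the lines' differences across genes (r = 0.41), which an exchange would turn negative if the lines respond alike. An exchange in both lines is not excluded by that value. Probe sets that do not read the introduced transcripts may be the reason and stay open: the largest difference at a line's own introduced gene was 0.090, which decides nothing without the sequences of probes and constructs. No biological explanation was tested.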

How the results depend on the processing

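The uninduced array of the other line as the reference, leaving out the two-cell-like list, removing the length trend and leaving out each array were chosen after seeing the data, and the others before. Where a count of genes moved with a threshold, filter or offset, that follows from how the alternative is built; for the other results below the cause was not tested. In this part, pairs of counts are genes higher, then lower. Cyclic loess, median centring, removing the length trend and leaving out the two-cell-like list kept every count of 2-fold genes they were run on within 1.5 times, and the correlation of the lines stayed between 0.32 and 0.48. The differences of the Hey1 and Hey2 probe sets moved by less than the spread of the uninduced difference (0.29) under cyclic loess and the offset. The common-response fit was paired, with the line as the replicate block, and without that block limma called 0 and 0 genes (268 and 203 at an unadjusted p of 0.05). Depth has no counterpart here, and nothing is said of the 6096 genes below the level filter.

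At 1.5-fold the counts were 222 and 71 in the Hey1 line, 365 and 298 in the Hey2 line, 544 and 535 between uninduced lines, 93 and 27 in both lines and 600 for differing responses. At 3-fold they were 16 and 1, 8 and 4, 20 and 34, 1 and 0, and 18. With the filter at the 75th percentile they were 21 higher in the Hey1 line, 28 and 18 in the Hey2 line, 63 and 61 between uninduced lines, 4 higher in both and 22 for differing responses. With the offset of 32 they were 30 higher in the Hey1 line, 35 and 17, 61 and 78, 4 and 2, and 33. With every probe set they were 9 lower in the Hey1 line, 173 higher in the Hey2 line, 158 and 260 between uninduced lines and 172 for differing responses. The mean of probe sets gave 55 higher in the Hey2 line and 63 higher in the uninduced Hey2 line, and no level filter gave 131 differing responses. With the uninduced array of the other line they were 252 and 135 in the Hey1 line and 135 and 94 in the Hey2 line.

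The common response had 0 and 0 genes at an adjusted p of 0.05 and also at 0.1, 241 and 192 with the trended robust prior, and 3 and 1 with the filter at the 75th percentile. Leaving out each array, in limma fits without the block because 3 arrays with it leave no residual degree of freedom, gave 0 to 5 higher and 0 to 0 lower. The 5 came without the Hey2 induced array: Pramel18, Ubtfl1, BC080696, Gm11544 and 3110040M04Rik. In these fits the lone array of an arm is assumed to vary like the others. Without the Hey2 induced array, the fit sets the Hey1 induced array alone against both uninduced arrays. Its calls are therefore not genes of a common response. Within the Hey2 line Pramel18 and Ubtfl1 differed by only 0.26 and -0.02.

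The following single differences changed sign against the uninduced array of the other line. In the Hey1 line these were Zic2 (0.055), Zic5 (0.31) and Rnf128 (-0.89). In the Hey2 line they were St8sia6 (-0.71), Prss35 (-0.82), Acta2 (1.12), Ptgs2 (-0.64), Slc25a31 (-0.037), Gsta3 (-0.65), Myl9 (0.99) and Cntnap2 (-1.39). Another 131 differences of named genes moved by more than the spread of the uninduced difference there, 34 with the offset and 22 with the mean of probe sets, and 0 with cyclic loess or median centring.

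List percentiles that crossed a bound of the random range were as follows. Without the level filter the Hey-repressed list lay at 13.2 (Hey2 line), the cardiac list at 75.9 (Hey1 line) and 2.74 (Hey2 line), the BMP and TGF-beta list at 16.8 (Hey2 line) and the imprinted list at 97.51 (Hey2 line). With the stricter filter the Notch list lay at 0.94, the Hey-repressed list at 1.03 and the trophoblast list at 99.7 in the Hey1 line, and the fibroblast list at 0.12 in the Hey2 line. After cyclic loess the cardiac list lay at 94.7 and 3.39. With the mean of probe sets the Notch list lay at 0.03, the cardiac list at 93.0, the endoderm list at 99.0 and the fibroblast list at 97.6 in the Hey1 line, and the Hey-repressed list at 2.80 and the neuroectoderm list at 0.16 in the Hey2 line. With every probe set the Hey-repressed list lay at 0.02 and the imprinted list at 97.7 in the Hey1 line, and the neuroectoderm list at 0.10 and the fibroblast list at 0.40 in the Hey2 line. With unmatched random lists the naive list lay at 3.62 in the Hey1 line, and the mesoderm list at 1.00 and the fibroblast list at 0.32 in the Hey2 line. Against the uninduced array of the other line the naive list lay at 26.1, the p53 list at 6.31 and the hypoxia list at 99.99 in the Hey1 line. In the Hey2 line the Hey-repressed list lay at 7.06, the epiblast list at 0, the two-cell-like list at 0.06, the hypoxia list at 0.01 and the imprinted list at 99.8.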

Other observations

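The tests of the germline and serum response factor lists were set after the pattern was noticed but before their results were seen, and that of the stress response was chosen after its result was seen.

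Germline genes were higher as a group in the arrays labelled induced of both lines. A list of 36 such genes, which left out every gene already seen among the largest differences, had 23 members above the level filter, with medians of 0.37 in the Hey1 line and 0.35 in the Hey2 line. Both lay above all level-matched random lists (100th percentile), and 21 and 19 of the 23 members were above 0. The piRNA pathway genes Rnf17 (0.80 in the Hey1 line and 1.19 in the Hey2 line) and Piwil2 (0.83 and 0.61), the germ cell genes Dazl (0.79 and 0.89) and Ddx4 (0.46 and 0.65), the oogenesis factor gene Sohlh2 (1.05 and 0.82) and the synaptonemal complex gene Sycp3 (1.17 and 0.54) were among them. A shift of germline genes as a set describes this pattern and does not explain it. The list was drawn up after the pattern was seen in these same arrays, so its percentiles are not independent support. It is given here only under the main settings and against the uninduced array of the other line. The uninduced arrays differed too, by a median of -0.23 (Hey2 line minus Hey1 line). With the uninduced array of the other line as the reference the medians were 0.64 and 0.14, at the 100th and 98.7th percentiles, with 14 of 23 members above 0 in the Hey2 line. Whether induction, doxycycline or 48 h of further culture gave the shift was not tested.

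Smooth muscle and cytoskeletal genes that depend on serum response factor were lower in the Hey2-line array labelled induced. The 18 compared members of a list that left out Acta2, Tagln and Myl9 had a median of -0.28 there, the lowest against all random lists (0th percentile), and of -0.03 in the Hey1 line (33.6th percentile). Tpm1 had -0.76, Csrp1 -0.82, Fhl2 -0.55 and Vcl -0.51 in the Hey2 line. The fibroblast markers, which hold Acta2 and Tagln, moved with them: their Hey2-line median was -0.31 with 1 of 9 members above 0, and 7 of 9 were higher in the uninduced Hey2 line. That list lay at the 2.83th percentile, inside the random range, and at 0.12 to 0.40 under 3 of the alternatives. Under the other alternatives it lay further inside, at 3.2 to 12.6, apart from median centring, which left it at 2.83. A shift of these targets as a set may describe the pattern, but it rests on the uninduced Hey2-line array, in which the list was already higher than in the uninduced Hey1 line by 0.34 (100th percentile). Against the uninduced array of the Hey1 line the Hey2-line median was 0.20, at the 99.8th percentile, with the opposite sign. A high state of the uninduced Hey2-line culture is therefore as open as an effect of induction.

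Doxycycline alone, which inhibits mitochondrial translation and can raise Atf4 targets, was considered for the stress response genes, since no array of cells without a transgene was analysed here. With an equal effect in both lines, the lines should differ by no more than random lists do. The median of the members' Hey2-line difference minus their Hey1-line difference was 0.22, above all random lists (100th percentile), and 17 of 20 members were higher on that measure. Random lists do not measure how far a co-regulated set varies between cultures, and with 1 array per group that variation is not known. An equal effect of doxycycline, an effect that differs between the lines and an effect of the Hey factors therefore all stay open.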
